A study of Mus musculus with 26 samples.

How the data were processed

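Gene expression had been measured on 26 Affymetrix arrays of mouse entorhinal cortex and hippocampus, 13 per region. The labels describe dissected, snap-frozen tissue and biotinylated complementary RNA prepared by the standard Affymetrix protocol. The log2 values were deposited by the authors as 1 table for all arrays, made with RMA (robust multi-array average, which corrects background, quantile-normalizes and summarizes the probes of a probe set) per the submitters' processing notes. The version of RMA and a genome build are not given in the sources used here. The table held 45101 probe sets per array with 0 missing values and 0 arrays with identical values. Because RMA forces the arrays to a common distribution, array medians lay between 5.51 and 5.58, and a change shared by most genes would not be visible. Log2 differences of dim probe sets are compressed by this kind of summary. The number of arrays limits the precision, and no batch is named in the labels used here.

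Groups came from the labels, which call the replicates of a group biological. They were transgenic with BDNF (n = 4), transgenic with GFP (n = 4), non-transgenic with GFP (n = 2) and non-transgenic sham (n = 3) in each region. The labels used here do not tie an entorhinal array to a hippocampal array of the same animal. Gene symbols came from the platform annotation, in which 34958 probe sets had 1 symbol, 932 had several and 9211 had no entry. Of those with 1 symbol, 34741 were updated through Entrez identifiers with a gene table of assembly GRCm38.p6, which was used for names and gene order only. No gene was named from a probe set with several symbols or none. Each of 18193 genes was represented by its probe set with the highest mean over all arrays, and genes whose mean lay below the 30th percentile of all probe sets (4.33) were left out, leaving 14940 genes. Probe sets of a gene can differ, and the values of the others are given where they read differently for a gene described in detail.

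Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to the deposited log2 values, with the 13 arrays of a region and their 4 groups in 1 fit, so that the groups share an estimate of the spread. Fits comparing regions used all 26 arrays and 8 groups. Comparisons were BDNF against GFP in transgenic mice, transgenic GFP against non-transgenic GFP and against all 5 non-transgenic arrays, transgenic BDNF against all non-transgenic arrays, and GFP against sham in non-transgenic mice, each per region. The difference of the BDNF effect and of the transgene effect between regions and the difference between the regions themselves were also tested. All tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Errors of log2 changes are moderated standard errors. The level of Xist was used as a covariate in an alternative fit, and arrays were divided into Xist classes at a log2 value of 7.

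A set of 30 gene lists of 570 genes was written before the data were examined, of which 517 genes had a probe set and 502 were tested. They cover signalling by neurotrophins, neuronal and glial cell types, other cell types that the tissue could hold, immune and metabolic pathways, and markers of brain regions. The list of erythrocyte genes had fewer than 4 tested genes and was not tested as a list, leaving 29. Lists were tested against all other genes with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. Benjamini-Hochberg adjustment over the list alone was computed for single members.

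Genes were named by a rule fixed before the data were examined. It took up to 10 genes per direction with the largest change among those called whose arrays did not overlap (6 for the comparison of regions), or, where a direction had fewer than 3, the 5 genes with the smallest p. It also took up to 4 passing members of each list described, or the 2 largest changes where none passed, and Bdnf, App, Ntrk2 and Gfap throughout. Further list members, and Cwc22, Galc, Fgf1, Pmaip1 and Creg2 where their levels are given across all groups, were chosen after their values were seen. The comparisons, main settings and most alternatives were also fixed before the data were examined. The alternatives were no filter, a filter at the 50th percentile, all probe sets 1 by 1, the mean of a gene's probe sets, renewed quantile normalization, centring on the array median, eBayes with trend and robust options, array weights, all 26 arrays in 1 fit, only the groups compared, the replicate number as a block, the Xist covariate and leaving out each array. Random-block list tests were not run for the comparisons that involve both regions. The mean of the MHC list as a covariate and all 10 vector-injected arrays against sham were added after seeing the data.

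The BDNF and transgene effects share the transgenic GFP arrays, so their covariance across genes was averaged over the ways of giving 2 of these arrays to each effect and set beside 1000 shuffles of the residuals. Correlations across arrays have permutation p-values from 100000 resamples. The models were tested on simulated data with independent noise of the observed spread and 200 of 14940 genes changed. For BDNF against GFP, 70.7% of genes changed by 0.5, 94.5% of those changed by 1 and 98.6% of those changed by 2 on the log2 scale were recovered in the entorhinal cortex, and 65.6%, 94.5% and 100% in the hippocampus. For GFP against sham these shares were 35.8%, 83.3% and 98.7% in the entorhinal cortex and 35.9%, 92.1% and 98.6% in the hippocampus. Real arrays also share variation across genes, which this simulation leaves out. Changing 200 genes at once also eases the Benjamini-Hochberg threshold, while comparisons within a region called only 0 to 8 real genes. Where few genes change, a smaller share would be recovered, so these shares do not give the power of the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.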

Results

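Messenger RNA was profiled on Affymetrix mouse arrays in the entorhinal cortex and hippocampus of aged mice that carry an amyloid precursor protein (APP) transgene, and of non-transgenic mice. A lentivirus encoding brain-derived neurotrophic factor (BDNF), a secreted neuronal growth factor that acts through the receptor TrkB, or green fluorescent protein (GFP) had been delivered to the entorhinal cortex, and tissue was taken 4 weeks later. In each region, 4 arrays came from transgenic animals given BDNF, 4 from transgenic animals given GFP, 2 from non-transgenic animals given GFP and 3 from non-transgenic animals with a sham lesion, making 26 arrays. Arrays are named here by group and replicate number. Their number limits the precision of every comparison. The 45101 probe sets on each array had log2 values between 2.19 and 13.99, with array medians between 5.51 and 5.58. Over all probe sets, 2 arrays of a region correlated at 0.984 to 0.997, and no array correlated above 0.989 with one of the other region. The mean over the myelin genes was 7.23 on entorhinal BDNF array 3 and 7.39 on entorhinal non-transgenic GFP array 2, against 7.99 to 8.78 on the other entorhinal arrays. The first of these arrays also had the highest mean over all probe sets in that region, 6.13 against 6.08 to 6.09. Hippocampal sham array 1 had a mean of 8.13 over choroid plexus genes, against at most 6.15 on the other hippocampal arrays. Xist, the RNA that silences an X chromosome in females, was high (10.38 to 11.01) on 18 arrays and low (5.38 to 6.01) on 8. All 10 non-transgenic arrays were in the high class, against 8 of the 16 transgenic arrays and 2 of 4 in each transgenic group.

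The first question was whether BDNF delivery changed expression in the injected entorhinal cortex of transgenic mice. Bdnf itself read 0.11 ± 0.21 higher on the log2 scale with BDNF than with GFP (SE, n = 4 and 4), and its second probe set read 0.09 ± 0.21. Whether these probe sets read the transcript of the vector is not given in the sources used here. Ntrk2, which encodes TrkB, read −0.09 ± 0.10, App 0.01 ± 0.05 and Gfap, the intermediate filament of astrocytes, 0.06 ± 0.25. Limma called 0 of 14940 genes, with 580 at an unadjusted p under 0.05 (343 higher and 237 lower), and the smallest adjusted p was 0.993. In each comparison of 14940 genes, 747 are expected at that level by chance. The genes with the smallest p included Tdo2 (0.60 ± 0.11), Htra1 (0.31 ± 0.06), Cwc22 (0.40 ± 0.09) and Slc5a5 (−1.05 ± 0.24).

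Of 29 gene lists, camera called 7 in that comparison, 1 higher and 6 lower with BDNF. The major histocompatibility complex (MHC) and antigen presentation list was lower in 14 of 14 genes, with a median log2 change of −0.38 (camera adjusted p = 0.0103). Its members included H2-Eb1 at −1.06 ± 1.06 and H2-Ab1 at −0.90 ± 0.90. Lymphocyte genes were lower in 13 of 13 (median −0.19, adjusted p = 0.0044), among them the immunoglobulin genes Ighm at −2.50 ± 1.32 and Jchain at −2.39 ± 1.19. Microglial genes were lower in 19 of 22 (−0.13, adjusted p = 0.0443), reactive astrocyte genes in 11 of 16 (−0.16, adjusted p = 0.0172) and meningeal genes in 14 of 14 (−0.18, adjusted p = 0.0173). Cholesterol synthesis genes were lower in 16 of 17 (−0.09, adjusted p = 0.0044), with Fdft1, the squalene synthase, at −0.21 ± 0.08. Astrocyte genes were higher in 14 of 15 (0.07, adjusted p = 0.0172), with the folate enzyme Aldh1l1 at 0.22 ± 0.09. Each of these 7 lists had adjusted p = 0.809 with an estimated correlation, fry called 0 lists (smallest adjusted p = 0.954), and 0 members passed adjusted over the list alone or over all genes. Leaving out BDNF array 2 or GFP array 4 left 1 list called, BDNF array 3 left 4 and BDNF array 1 gave 11. Without GFP array 4 the MHC median was −0.02, the lymphocyte median −0.02 and the microglial median 0.03. Without BDNF array 2 the MHC median was −0.18 and the lymphocyte median −0.07, and without BDNF array 3 the MHC median was −0.22, and each of these calls ended. The microglial, reactive astrocyte, astrocyte and meningeal calls each ended without BDNF array 2, BDNF array 3 or GFP array 4. The microglial call also ended without BDNF array 4 or GFP array 3, the astrocyte call without GFP array 3 and the meningeal call without GFP arrays 1 or 2. The cholesterol call ended without BDNF array 1 (−0.05) or GFP array 3 (−0.03). Genes of BDNF and TrkB signalling (median −0.02), activity-regulated early genes (0.01), neurotrophin-responsive genes (−0.06), presynaptic genes (0.00), glutamate receptor genes (−0.03) and amyloid processing genes (0.01) were not called, with camera adjusted p from 0.105 to 0.861. For the early genes (mean −0.02) and presynaptic genes (mean −0.01) the mean and the test pointed lower although the medians were not below 0.

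In the hippocampus, which receives axons from the entorhinal cortex, Bdnf read −0.14 ± 0.17 with BDNF against GFP (SE, n = 4 and 4) and −0.14 ± 0.20 on its second probe set. App read 0.03 ± 0.06, Ntrk2 0.02 ± 0.10 and Gfap −0.60 ± 0.25, an adjusted p of 0.901. Limma called 0 of 14940 genes, with 793 at an unadjusted p under 0.05 (274 higher and 519 lower), where 747 were expected by chance. The smallest adjusted p, 0.110, was that of Acer2, an alkaline ceramidase, at −0.48 ± 0.07. Rhog read −0.42 ± 0.07, Chil1 −0.46 ± 0.09 and Oxtr, the oxytocin receptor, 0.40 ± 0.10.

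Camera called 8 lists there, 7 lower and 1 higher with BDNF. MHC genes were lower in 14 of 14 (median −0.71, camera adjusted p = 7.83e-07), including H2-Aa at −1.63 ± 0.89 and Cd74, the invariant chain of class II molecules, at −1.54 ± 0.91. Interferon response genes were lower in 20 of 20 (−0.44, adjusted p = 3.95e-07), including Oasl2 at −1.06 ± 0.47 and Ifit3 at −0.88 ± 0.36. Microglial genes were lower in 20 of 22 (−0.36, adjusted p = 3.26e-08), including the complement gene C1qa at −0.64 ± 0.24, and genes of plaque-associated microglia in 17 of 20 (−0.24, adjusted p = 3.43e-05), including Clec7a at −1.31 ± 0.50. Myelin genes were lower in 15 of 15 (−0.28, adjusted p = 3.26e-08), including Mog at −0.43 ± 0.20. Reactive astrocyte genes were lower in 13 of 16 (−0.26, adjusted p = 0.00032) and lymphocyte genes in 10 of 13 (−0.16, adjusted p = 0.0107), with Ighm at −3.10 ± 1.03. These 7 lists had adjusted p = 0.592 with an estimated correlation. Genes of GABAergic interneurons were higher in 13 of 16 (0.09, adjusted p = 0.00662), with adjusted p = 0.736 with an estimated correlation, and included the cannabinoid receptor Cnr1 at 0.20 ± 0.09. Adjusted over the list alone, 3 myelin genes passed (Aspa −0.39, Fa2h −0.28, Ppp1r14a −0.43) and 2 reactive astrocyte genes (Aspg −0.28, Cd14 −0.37), against 0 over all genes. The GABAergic call ended without GFP array 2 (0.05), GFP array 3 (0.06) or BDNF array 3 (0.06), the reactive astrocyte call without GFP array 2 (−0.12) or BDNF array 3 (−0.23), and the lymphocyte call without GFP arrays 2 or 3 or BDNF arrays 3 or 4. Without BDNF array 3, 5 lists were called. The MHC median was −1.11 without GFP array 4, which had the lowest MHC mean of its group, and −0.47 without GFP array 2, the interferon median −0.59 and −0.36, and the microglial median −0.52 and −0.23, and these calls remained. With each array's MHC mean as a covariate, an alternative chosen after seeing the data, the calls of the microglial (−0.10), plaque-associated (−0.11), reactive astrocyte (−0.08), lymphocyte (0.00), interferon (−0.06) and GABAergic (0.02) lists ended. Genes of BDNF and TrkB signalling (0.00), early genes (−0.14), neurotrophin-responsive genes (−0.02), presynaptic genes (0.00), glutamate receptor genes (−0.02) and amyloid processing genes (0.01) were not called, with camera adjusted p from 0.113 to 0.900. For the amyloid genes the mean (−0.02) and the test pointed lower against the median, and for BDNF and TrkB signalling the mean (−0.01) was below 0 although the test pointed higher.

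Whether the BDNF effect differed between the regions was tested directly over all 26 arrays. Limma called 0 genes, with 602 at an unadjusted p under 0.05, and the smallest adjusted p, 0.863, was that of Trpc7 (−0.69). Only the GABAergic list was called by camera, lower in 12 of 16 genes in the entorhinal effect than in the hippocampal effect (median −0.09, adjusted p = 0.0433), with adjusted p = 0.831 with an estimated correlation. Leaving out 1 array gave from 0 to 7 called lists, and the GABAergic call ended, with medians of −0.03 to −0.10, without entorhinal BDNF arrays 1 or 3, entorhinal GFP arrays 1, 2 or 3, hippocampal BDNF arrays 2, 3 or 4 or hippocampal GFP arrays 2 or 3.

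The effect of the transgene was read from the GFP arrays. In the entorhinal cortex, 2 genes differed between transgenic GFP arrays and all non-transgenic arrays (n = 4 and 5). Thy1, a cell surface glycoprotein of neurons and T cells, rose by 1.35 ± 0.06 (SE, limma adjusted p = 3.81e-07). It lay between 13.67 and 13.80 on transgenic GFP arrays and between 12.30 and 12.46 on non-transgenic arrays. St13, a cochaperone of Hsp70, fell by 0.77 ± 0.06 (limma adjusted p = 0.000296). It lay between 11.62 and 11.74 on non-transgenic arrays and between 10.88 and 10.97 on transgenic GFP arrays. A second St13 probe set read −1.05 and the third −0.10, while Thy1 had 1 probe set. App read −0.01 ± 0.05, Bdnf −0.05 ± 0.20, Ntrk2 0.02 and Gfap −0.10 ± 0.23. Whether the App probe sets read the transgene is not given in the sources used here. Against the 2 non-transgenic GFP arrays alone, Thy1 (1.42 ± 0.08) and St13 (−0.76 ± 0.08) were again the 2 genes called, and St13 lost its call when either of those arrays was left out (−0.72 without array 1 and −0.80 without array 2). Against all non-transgenic arrays, 4 genes were called without non-transgenic GFP array 1.

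Cholesterol synthesis genes were higher in 16 of 17 in the entorhinal cortex of transgenic mice (median 0.19, camera adjusted p = 8.13e-11), with adjusted p = 0.262 with an estimated correlation. Fdft1 read 0.44 ± 0.08, the farnesyl diphosphate synthase Fdps 0.38 ± 0.10, and the squalene epoxidase Sqle 0.29 ± 0.07. These were among 6 genes that passed adjusted over the list alone, against 0 over all genes. Against non-transgenic GFP arrays alone the list was higher in 17 of 17 (0.29, adjusted p = 1.99e-14), with adjusted p = 0.30 with an estimated correlation and 6 genes adjusted over the list alone. The list means were 9.04 on transgenic GFP, 8.77 on non-transgenic GFP and 8.88 on sham arrays. On single arrays the list mean ranged from 8.84 to 9.23 with transgenic GFP and from 8.85 to 8.91 with sham, so not every transgenic array was raised over sham. MHC genes were higher in 14 of 14 against all non-transgenic arrays (0.85, adjusted p = 0.000294; adjusted p = 0.801 with an estimated correlation), a call that ended without transgenic GFP array 4 (0.34). Neurotrophin-responsive genes were lower in 18 of 24 (−0.12, adjusted p = 0.00649; adjusted p = 0.262 with an estimated correlation), which ended without the same array (−0.07). Neither list was called against non-transgenic GFP arrays alone, where MHC genes were lower in 9 of 14 (−0.02, adjusted p = 0.886) and neurotrophin-responsive genes in 13 of 24 (−0.03, adjusted p = 0.943). The means over MHC genes were 8.72 on transgenic GFP, 8.74 on non-transgenic GFP and 7.29 on sham arrays, and those over neurotrophin-responsive genes were 8.846, 8.842 and 8.998. Camera called 11 lists against all non-transgenic arrays and 5 without transgenic GFP array 4. Against non-transgenic GFP arrays alone it called 2, and 13, 7 or 8 without non-transgenic GFP array 1, non-transgenic GFP array 2 or transgenic GFP array 4.

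In the hippocampus, 6 genes differed between transgenic GFP arrays and all non-transgenic arrays (n = 4 and 5), 3 in each direction. With Xist as a covariate, 3 genes were called. Thy1 rose by 1.27 ± 0.05 (limma adjusted p = 5.46e-08), from 12.56 to 12.67 on non-transgenic arrays to 13.84 to 13.99 on transgenic arrays. St13 fell by 0.78 ± 0.10 (adjusted p = 0.00995), and its other probe sets read −0.95 and −0.21. Stard4, a sterol transfer protein, rose by 0.60 ± 0.08 (adjusted p = 0.0159). Pmaip1, a proapoptotic protein, rose by 0.85 ± 0.09 (adjusted p = 0.00339) and Fgf1, acidic fibroblast growth factor, fell by 0.51 ± 0.07 (adjusted p = 0.0154). For both of these the non-transgenic GFP arrays lay on the transgenic side of the sham arrays. Mgp, an inhibitor of tissue calcification, fell by 0.75 ± 0.10 (adjusted p = 0.0119). App read −0.01 ± 0.06, Bdnf 0.01 ± 0.16, Ntrk2 0.07 and Gfap 0.26 ± 0.24. Against non-transgenic GFP arrays alone only Thy1 was called (1.29 ± 0.07), with Stard4 at 0.71 ± 0.11 and St13 at −0.79 ± 0.12. Thy1 and St13 were called in both regions against all non-transgenic arrays, where 0.000803 shared genes were expected for independent lists. The lists are not independent, since the changes in the 2 regions correlated at r = 0.554 over all genes and the regions may share animals. Against all non-transgenic arrays the number of genes called was 10, 3, 1 and 3 without transgenic GFP array 3, transgenic GFP array 4, sham array 2 and sham array 3. Without sham array 2 the St13 and Pmaip1 (0.72) calls ended. Stard4 lost its call without transgenic GFP arrays 1 or 4, non-transgenic GFP array 2 or sham arrays 2 or 3, and Mgp and Fgf1 lost theirs without any of the sham arrays or transgenic GFP array 4. Against non-transgenic GFP arrays alone, 2, 2 and 5 genes were called without transgenic GFP array 1, non-transgenic GFP array 1 and transgenic GFP array 2.

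Hippocampal cholesterol synthesis genes were higher in 16 of 17 in transgenic mice (median 0.31, camera adjusted p = 8.78e-18), with adjusted p = 0.0891 with an estimated correlation and 0.0618 by fry. Adjusted over the list alone 12 genes passed, among them Fdft1 (0.57 ± 0.12), Sqle (0.43 ± 0.09), the isopentenyl diphosphate isomerase Idi1 (0.41 ± 0.13) and Hmgcs1 (0.31 ± 0.07), against 1, Stard4, over all genes. Against non-transgenic GFP arrays alone the list was higher in 17 of 17 (0.45, adjusted p = 1.45e-17; adjusted p = 0.132 with an estimated correlation), again with 12 genes adjusted over the list alone. The list means were 9.001 on transgenic GFP, 8.58 on non-transgenic GFP and 8.76 on sham arrays, so the lower level with the GFP vector in non-transgenic mice enlarged this contrast. On single arrays the list mean ranged from 8.72 to 9.23 with transgenic GFP and from 8.72 to 8.81 with sham, so not every transgenic array was raised over sham. MHC genes were higher in 14 of 14 against all non-transgenic arrays (0.39, adjusted p = 0.000754; adjusted p = 0.604 with an estimated correlation) and lower in 14 of 14 against non-transgenic GFP arrays (−0.55, adjusted p = 6.3e-05; adjusted p = 0.680 with an estimated correlation). The first of these calls ended without sham array 1 (0.19), sham array 2 (0.19), transgenic GFP array 2 (0.19) or transgenic GFP array 3 (0.33), and the second without non-transgenic GFP array 1 (0.05) or transgenic GFP array 4 (−0.12). Microglial genes were higher in 21 of 22 against all non-transgenic arrays (0.19, adjusted p = 0.00116; adjusted p = 0.670 with an estimated correlation), a call that ended without transgenic GFP array 2 (0.10) or sham array 2 (0.15). They were higher in 11 of 22 against non-transgenic GFP arrays alone and not called (0.00, adjusted p = 0.593), with means of 8.75 on transgenic GFP, 8.76 on non-transgenic GFP and 8.45 on sham arrays. Camera called 10 lists against all non-transgenic arrays, 6 without transgenic GFP array 3, and 7 against non-transgenic GFP arrays, 12 without transgenic GFP array 2. The test of the difference between regions called 0 genes by limma (301 at an unadjusted p under 0.05). It called the cholesterol list, with a smaller effect in the entorhinal cortex in 13 of 17 genes (−0.12, camera adjusted p = 0.0161; adjusted p = 0.989 with an estimated correlation). That call ended without entorhinal transgenic GFP array 1 (−0.07), entorhinal sham array 3 (−0.10), hippocampal transgenic GFP arrays 1 (−0.07) or 4 (−0.03), or hippocampal non-transgenic GFP array 1 (−0.08).

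**Figure D1:**
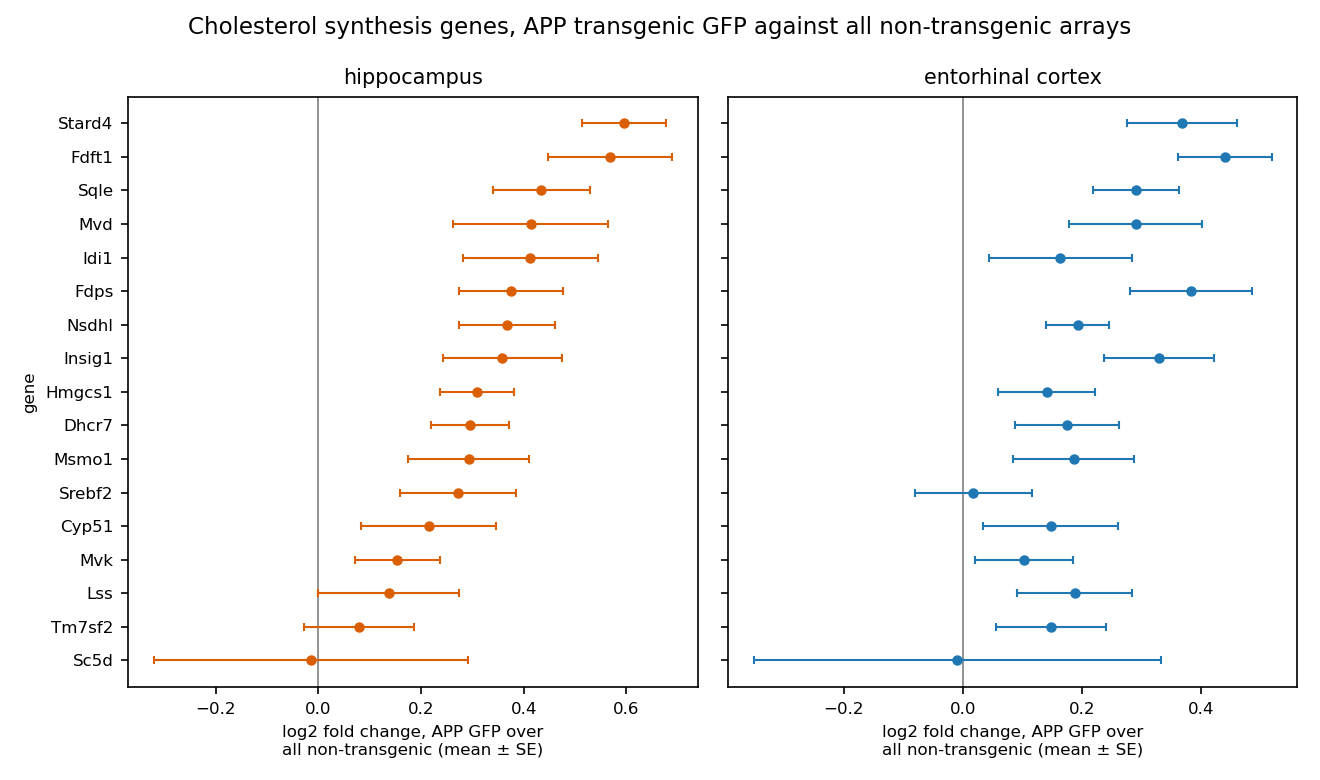
Log2 change of the 17 cholesterol synthesis genes in transgenic GFP arrays over all non-transgenic arrays (point, with SE as bar; n = 4 and 5), in the hippocampus on the left and the entorhinal cortex on the right. In each region 16 of the 17 points lie above 0, and Sc5d lies near 0 with a wide error.

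Transgenic mice given BDNF were next set against all non-transgenic arrays (n = 4 and 5). In the entorhinal cortex 6 genes differed, 3 in each direction, and 3 were called with Xist as a covariate. There were 1967 at an unadjusted p under 0.05 (1291 higher and 676 lower, and 1286 in all without sham array 2), where 747 were expected by chance. Thy1 rose by 1.29 ± 0.06 (limma adjusted p = 6.6e-07), Cwc22, a spliceosome protein, by 0.82 ± 0.09 (adjusted p = 0.00303) and Pmaip1 by 1.43 ± 0.21 (adjusted p = 0.0453). St13 fell by 0.76 ± 0.06 (adjusted p = 0.000345), Galc, the lysosomal galactosylceramidase, by 0.62 ± 0.08 (adjusted p = 0.0218) and the protocadherin Pcdhb9 by 0.55 ± 0.07 (adjusted p = 0.0218). For Cwc22 and Galc the difference lay between sham and vector-injected arrays, with means of 8.07 and 7.45 with BDNF, 7.92 and 7.55 on non-transgenic GFP arrays and 6.81 and 8.42 on sham arrays. Pmaip1 averaged 6.56, 5.83 and 4.65, and Pcdhb9 8.35, 8.63 and 9.08, in these groups. Thy1 and St13 were called without any 1 array. Cwc22 lost its call without sham arrays 1 (0.71) or 2 (0.70), Pmaip1 without BDNF arrays 1, 2 or 3 or any sham array, Pcdhb9 without BDNF arrays 1 or 2 or any sham array, and Galc without BDNF array 4 or any sham array. The count was 10 without non-transgenic GFP array 1 and 2 without sham array 1 or sham array 2. Neurotrophin-responsive genes were lower in 19 of 24 (median −0.13, camera adjusted p = 0.000661; adjusted p = 0.140 with an estimated correlation), and the neuropeptide genes Tac1 (−0.43 ± 0.12), Cort (−0.38) and Npy (−0.37) passed adjusted over the list alone, against 0 over all genes. The mean over this list was 8.801 with BDNF, 8.842 on non-transgenic GFP arrays and 8.998 on sham arrays. Glutamate receptor genes were lower in 15 of 19 (−0.08, adjusted p = 0.0252; adjusted p = 0.862 with an estimated correlation), with Gria3 (−0.48 ± 0.14) and Grin2b (−0.40 ± 0.11) lower and Gria4 (0.38) higher adjusted over the list alone. The glutamate call ended without BDNF array 1 (−0.07) or non-transgenic GFP array 2 (−0.05). Cholesterol synthesis genes were higher in 15 of 17 (0.10, adjusted p = 0.00898; adjusted p = 0.862 with an estimated correlation), which ended without BDNF array 2 (0.09) or non-transgenic GFP array 1 (0.06).

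In the hippocampus 8 genes differed, 4 in each direction, with 985 at an unadjusted p under 0.05. With Xist as a covariate, only 1 gene was called. Thy1 rose by 1.27 ± 0.05 (limma adjusted p = 5.3e-08), Cwc22 by 0.62 ± 0.07 (adjusted p = 0.0114), Stard4 by 0.62 ± 0.08 (adjusted p = 0.0208) and Pmaip1 by 0.63 ± 0.09 (adjusted p = 0.0294). St13 fell by 0.66 ± 0.10 and Acer2 by 0.43 ± 0.06 (both adjusted p = 0.0294), Klf2, a transcription factor of endothelial cells, by 0.62 ± 0.09 (adjusted p = 0.0326) and Fgf1 by 0.47. Cwc22 and Pmaip1 were no higher than on non-transgenic GFP arrays, with means of 7.72 and 6.15 with BDNF, 7.80 and 6.30 on non-transgenic GFP arrays and 6.63 and 5.002 on sham arrays, and Fgf1 averaged 8.25, 8.20 and 9.06. Thy1 was called without any 1 array, but the count fell to 1 without BDNF arrays 1, 2 or 3 or sham arrays 2 or 3, to 2 without BDNF array 4 or sham array 1 and to 4 without non-transgenic GFP array 2. Thy1, St13, Cwc22 and Pmaip1 were called in both regions, where 0.00321 shared genes were expected for independent lists. The lists are not independent, since the changes in the 2 regions correlated at r = 0.225 over all genes and the regions may share animals. Cwc22 and Pmaip1 also set sham arrays apart from all vector-injected arrays in both regions. Cholesterol synthesis genes were higher in 16 of 17 (median 0.23, camera adjusted p = 1.99e-11; adjusted p = 0.206 with an estimated correlation), with 7 genes adjusted over the list alone, among them Fdft1 (0.52 ± 0.12) and Sqle (0.46 ± 0.09), against 1, Stard4, over all genes. Myelin genes were lower in 15 of 15 (−0.25, adjusted p = 4.19e-09; adjusted p = 0.280 with an estimated correlation), with Mal at −0.40 ± 0.13 and Aspa at −0.36 ± 0.12, and 0 genes passed adjusted over the list alone. Interferon response genes were lower in 19 of 20 (−0.31, adjusted p = 8.49e-06; adjusted p = 0.511 with an estimated correlation), which ended without non-transgenic GFP array 1 (−0.16). Camera called 16 lists, 3 higher and 13 lower, and 7 without non-transgenic GFP array 1.

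Whether BDNF moved genes opposite to the transgene was asked over 14940 genes. Because the transgenic GFP arrays enter both effects, they were split so that no array served both. The covariance of the BDNF effect and the transgene effect was 0.00395 in the entorhinal cortex (r = 0.123 across genes, which are not independent replicates), against −0.000435 in 1000 shuffles of the residuals, 95% of which lay between −0.0180 and 0.0131. In the hippocampus it was 0.00188 (r = 0.0556), against −6.69e-05, with 95% between −0.00852 and 0.00834. Both values lay within what the shuffles gave. The entorhinal value ranged from 0.00188 without transgenic GFP array 2 to 0.00591 without BDNF array 3. The hippocampal value ranged from −0.00431 without transgenic GFP array 4 to 0.00723 without transgenic GFP array 2. Of the genes called between transgenic GFP and all non-transgenic arrays, Thy1 and St13 had BDNF effects of opposite sign in the entorhinal cortex (−0.06 and 0.01). In the hippocampus 4 of 6 had the opposite sign, namely St13 (0.12), Pmaip1 (−0.22), Mgp (0.29) and Fgf1 (0.05). Against non-transgenic GFP arrays alone, Pmaip1 read 0.07 and Fgf1 0.01 there. The signs of these 2 genes therefore do not bear on whether BDNF opposed the transgene. Among genes with an unadjusted p under 0.05 for the transgene, 65.7% in the entorhinal cortex and 81.4% in the hippocampus had a BDNF effect of opposite sign. With the transgenic GFP arrays shared, 100 shuffles gave means of 88.2% (42.8 to 100) and 87.4% (56.2 to 100).

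Non-transgenic mice given the GFP vector were set against non-transgenic mice with a sham lesion (n = 2 and 3). In the entorhinal cortex 3 genes differed. Cwc22 rose by 1.11 ± 0.12 (SE, limma adjusted p = 0.00936), from 6.81 ± 0.04 (SD) on sham arrays to 7.92 ± 0.22. Galc fell by 0.87 ± 0.11 and Fgf1 by 0.77 ± 0.10 (both adjusted p = 0.0222). Both transgenic groups had levels of these genes nearer to the non-transgenic GFP arrays than to the sham arrays. Galc lay between 8.37 and 8.49 on sham arrays and between 7.19 and 7.62 on the other entorhinal arrays. The other Galc probe sets, which were dim, read 0.01 and −0.08, and the other Fgf1 probe sets −0.56 and 0.25. Leaving out any of the 5 arrays ended the Galc and Fgf1 calls, and Cwc22 lost its call without any sham array or non-transgenic GFP array 1 (0.95), so that 0 genes were called without each of those 4 and 1 without non-transgenic GFP array 2. Without a non-transgenic GFP array 1 array remained, which is assumed to vary like the other groups. With each array's MHC mean as a covariate, added after seeing the data, Cwc22 read 1.08 ± 0.14, Galc −0.93 ± 0.13 and Fgf1 −0.79 ± 0.12, and 0 genes were called by limma (586 at an unadjusted p under 0.05) as the errors widened.

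MHC genes were higher in 14 of 14 with the vector (median 1.34, camera adjusted p = 3.14e-09), including Cd74 at 2.79 ± 1.18 and H2-Ab1 at 2.71 ± 1.16. Lymphocyte genes were higher in 11 of 13 (0.55, adjusted p = 6.99e-06), including the immunoglobulin genes Jchain at 4.96 ± 1.54 and Ighm at 3.07 ± 1.70. Both lists had adjusted p = 0.510 with an estimated correlation. Interferon response genes were higher in 20 of 20 (0.39, adjusted p = 7.38e-05; adjusted p = 0.807 with an estimated correlation). These calls rested on non-transgenic GFP array 1, without which the medians were 0.27 for MHC, 0.12 for lymphocyte and −0.28 for interferon genes. Endothelial genes were lower in 16 of 17 (−0.22, adjusted p = 5.02e-07; adjusted p = 0.333 with an estimated correlation), and the tight junction gene Cldn5 (−0.35 ± 0.08) passed adjusted over the list alone, against 0 over all genes. Neurotrophin-responsive genes were lower in 21 of 24 (−0.14, adjusted p = 0.00039; adjusted p = 0.294 with an estimated correlation), a call that ended without non-transgenic GFP array 1 (−0.05). Cholesterol synthesis genes were lower in 11 of 17 (−0.08, adjusted p = 0.0408; adjusted p = 0.807 with an estimated correlation), which ended without non-transgenic GFP array 1 (−0.02) or sham arrays 2 (−0.07) or 3 (−0.05), and the median was −0.14 without non-transgenic GFP array 2.

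In the hippocampus 5 genes differed between the GFP vector and sham. Cwc22 rose by 1.16 ± 0.10 (limma adjusted p = 0.000544), Pmaip1 by 1.30 ± 0.12 (adjusted p = 0.000902) and Creg2 by 1.97 ± 0.27 (adjusted p = 0.017). Fgf1 fell by 0.87 ± 0.09 (adjusted p = 0.00238) and Galc by 0.93 ± 0.13 (adjusted p = 0.017). The microglial gene Fcrls read −2.04 ± 0.34 with an adjusted p of 0.0865. Creg2 averaged 8.02 ± 0.32 (SD) on sham arrays and 9.73 to 9.99 in the other groups. Cwc22, Fgf1 and Galc were called in both regions, where 0.001 shared genes were expected for independent lists. The lists are not independent, since the changes in the 2 regions correlated at r = 0.674 over all genes and the regions may share animals. Cwc22 and Pmaip1 were called without any 1 array, and the number of genes was 10, 2 and 3 without non-transgenic GFP array 1, non-transgenic GFP array 2 and sham array 3. Fgf1 lost its call without non-transgenic GFP array 2 (−0.72), Galc without either non-transgenic GFP array or sham arrays 1 or 3, and Creg2 without non-transgenic GFP array 2 or sham arrays 2 or 3. With the MHC mean as a covariate, Cwc22 read 1.16 ± 0.15, Pmaip1 1.19 ± 0.18, Creg2 2.28 ± 0.37, Fgf1 −0.86 ± 0.14 and Galc −0.94 ± 0.19, and limma called 0 genes (1120 at an unadjusted p under 0.05).

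Hippocampal MHC genes were higher in 14 of 14 (median 1.72, camera adjusted p = 7.67e-18), with Cd74 at 4.75 ± 1.18, H2-Aa at 4.57 ± 1.15 and the class I gene H2-D1 at 2.30 ± 0.61. Lymphocyte genes were higher in 11 of 13 (0.44, adjusted p = 3.23e-08), with Jchain at 7.06 ± 1.48, Ighm at 5.85 ± 1.33 and the chemokine Ccl5 at 2.61. Adjusted over the list alone 12 MHC and 7 lymphocyte genes passed, against 0 over all genes, and both lists had adjusted p = 0.304 with an estimated correlation. Interferon response genes were higher in 19 of 20 (0.52, adjusted p = 8.25e-09), genes of plaque-associated microglia in 16 of 20 (0.12, adjusted p = 1.34e-05) and reactive astrocyte genes had a median of 0.28 (adjusted p = 4.27e-05). These 3 lists had adjusted p = 0.588 with an estimated correlation. Microglial genes were higher in 18 of 22 (0.26, camera adjusted p = 1.51e-05, and 0.728 with an estimated correlation). With the MHC mean as a covariate, the medians of the interferon, plaque-associated, reactive astrocyte and microglial lists turned negative. The interferon and microglial calls ended without non-transgenic GFP array 1, each with a median of −0.04. Cholesterol synthesis genes were lower in 15 of 17 (−0.18, adjusted p = 0.0166; adjusted p = 0.801 with an estimated correlation), which ended without the same array (−0.11). On sham arrays the MHC mean lay between 7.15 and 7.50 in the entorhinal cortex and 7.09 and 7.40 in the hippocampus. The vector-injected arrays ranged from 7.46 to 9.97 and from 7.17 to 9.94, with 8 of 10 above the highest sham array in each region.

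**Figure D2:**
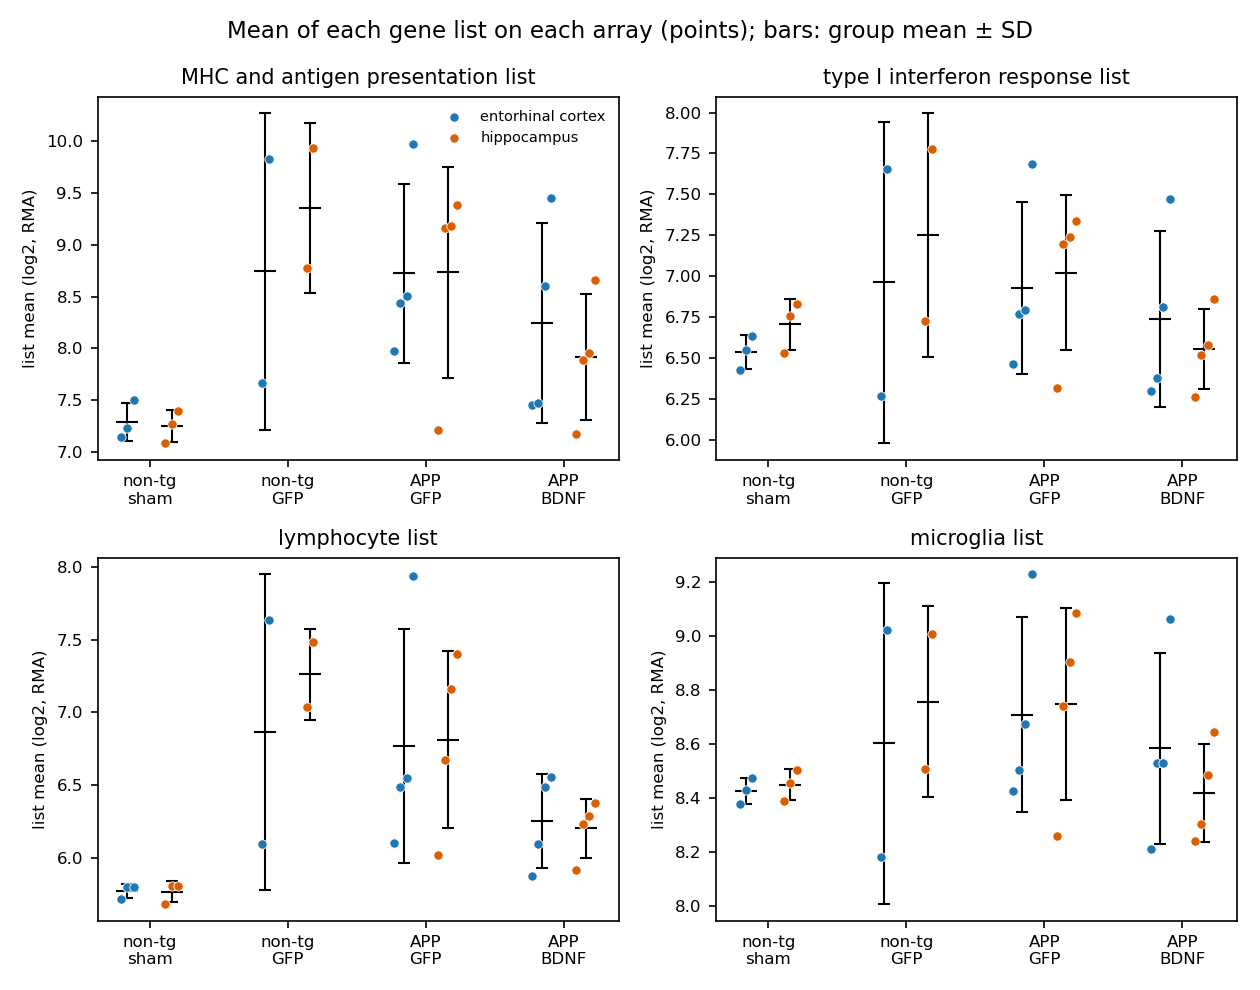
Mean log2 expression per array of the MHC, interferon response, lymphocyte and microglial gene lists by group, with entorhinal arrays in blue, hippocampal arrays in orange and bars for the group mean ± SD. The sham arrays lie together in the MHC panel, with SDs of 0.19 and 0.16, while the vector-injected groups spread by 0.61 to 1.53.

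**Figure D3:**
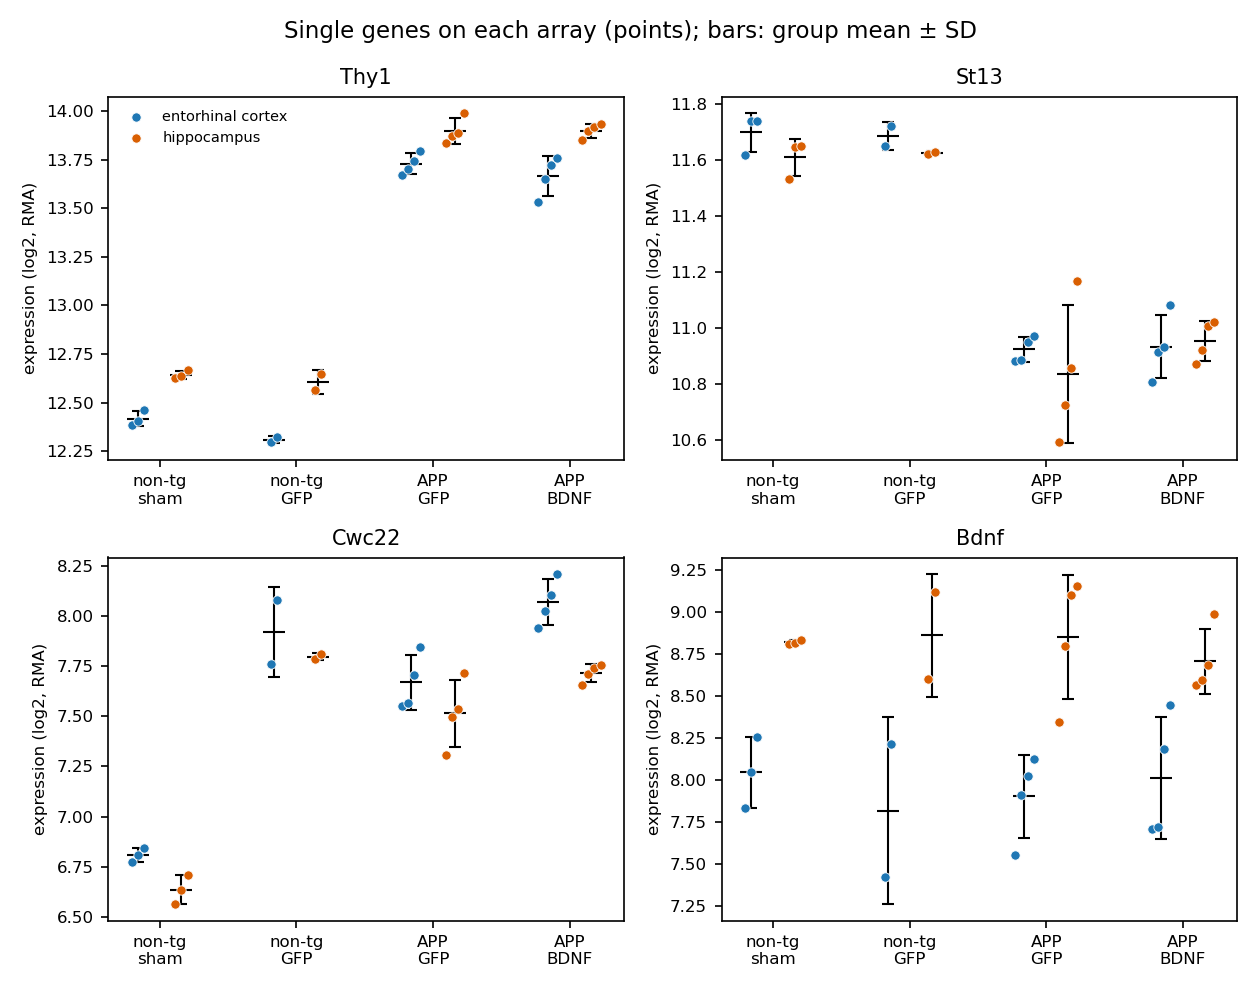
Log2 expression per array of Thy1, St13, Cwc22 and Bdnf by group, with entorhinal arrays in blue, hippocampal arrays in orange and bars for the group mean ± SD. Thy1 is higher and St13 lower on every transgenic array than on any non-transgenic array of the same region, and Cwc22 is lowest on the sham arrays.

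Entorhinal cortex and hippocampus were compared over all 26 arrays. Limma called 7748 genes, 3076 higher and 4672 lower in the entorhinal cortex. The largest differences included Ccn2, a matricellular protein, at 3.12 ± 0.18 (SE, n = 13 and 13), Slc26a7 at 2.96 ± 0.23 and the glycine receptor subunit Glra3 at 2.85 ± 0.12, and on the hippocampal side Dsp, the desmosomal protein desmoplakin, at −4.76 ± 0.17, Lct at −3.91 ± 0.14 and St18 at −3.81 ± 0.11. Bdnf was lower in the entorhinal cortex, at −0.87 ± 0.11 (adjusted p = 1.46e-06), and so was Gfap, at −1.46 ± 0.15 (adjusted p = 5.1e-08), while Ntrk2 was higher by 0.33 ± 0.06 (adjusted p = 6.36e-05) and App by 0.12 ± 0.03 (adjusted p = 0.00116). The labels used here do not tie the arrays of the regions to animals, so the arrays were treated as independent. The 3′ to 5′ log2 difference of the Actb control probe sets, a sign of RNA length, also moved with region, with group means of 1.92 to 2.03 in the entorhinal cortex and 1.48 to 1.58 in the hippocampus.

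Camera called 7 lists between the regions. Genes of CA1 and CA3 pyramidal cells were lower in the entorhinal cortex (median −1.01, camera adjusted p = 0.000273; adjusted p = 0.0104 with an estimated correlation), with 11 of 14 passing lower, such as the transcription factor Pou3f1 (−2.73 ± 0.18) and Fibcd1 (−2.01 ± 0.12), and 3 passing higher. Dentate granule cell genes had a median of −0.64 (adjusted p = 5.28e-05), with 11 of 14 lower, such as C1ql2 (−2.97 ± 0.17). Cortical layer genes had a median of 0.42 (adjusted p = 0.00326), with 9 of 16 higher, such as the homeobox gene Cux2 (2.01 ± 0.09), and 5 lower. Genes of striatum, thalamus and septum had a median of 0.56 (adjusted p = 0.00417), with the dopamine receptor Drd1 at 1.31 ± 0.15. Cytoskeletal and axon growth genes had a median of 0.15 (adjusted p = 0.00303), with 13 of 22 higher, such as the growth cone protein Gap43 (1.21 ± 0.06), and 4 lower, such as the neurofilament Nefm (−0.83 ± 0.05). These 4 lists had adjusted p = 0.136 with an estimated correlation. Myelin genes were lower in 15 of 15, 14 of which passed (−1.35, adjusted p = 2.17e-06; adjusted p = 0.467 with an estimated correlation), such as Mobp (−2.05 ± 0.28) and Mog (−1.87 ± 0.21). Meningeal genes were higher (0.94, adjusted p = 2.15e-05; adjusted p = 0.422 with an estimated correlation), with 12 of 14 passing higher, such as Fmod (2.63 ± 0.18). Fry, which does not compare a list with other genes, called 15 lists.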

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

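The tests of the explanations weighed in this part, on immune genes, on Thy1 and St13 and on the sham arrays, were all chosen after the results were seen.

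Over 180 combinations of a gene list or a single named gene with a group of 4 arrays, 5 arrays lay far from the others of their group by Dixon's ratio at its 95% critical value, which chance passes in about 1 in 20 groups. The plaque-associated microglia mean was 8.38 on entorhinal transgenic GFP array 4, against 7.28 to 7.45 on the others. On the same array the oxidative phosphorylation mean was 11.65, against 11.69 on each of the others. On hippocampal transgenic GFP array 4 the MHC mean was 7.22, against 9.16 to 9.38, and the interferon response mean was 6.32, against 7.20 to 7.34. The astrocyte mean was 10.50 on hippocampal BDNF array 3, against 10.49 on each of the others. The effects of BDNF on the GABAergic list (median difference −0.093, entorhinal minus hippocampal) and of the transgene on the choroid plexus list (0.28) and the cholesterol list (−0.12) differed between regions by camera's test of the difference, with adjusted p = 0.831 for the first and 0.989 for the other 2 with an estimated correlation. Without hippocampal sham array 1, which carried choroid plexus transcripts, the choroid plexus difference was −0.11, and its call also ended without entorhinal transgenic GFP array 1 (0.25) or hippocampal transgenic GFP arrays 1 (0.27) or 4 (0.25). Among 10092 probe sets without exactly 1 gene symbol, which no comparison of genes uses, limma called 1 between transgenic GFP and all non-transgenic arrays in the entorhinal cortex (1.20), 1 between BDNF and all non-transgenic arrays there (1.42), 1 between GFP and sham there (2.39) and 5 between GFP and sham in the hippocampus (at most 2.37). All of these were higher, and the same probe set was among them each time.

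Immune genes were high on some vector-injected arrays and on no sham array, with 8 of 10 vector-injected arrays above the highest sham array in the MHC mean in each region. Blood left in the tissue is argued against in the hippocampus and stays open in the entorhinal cortex: over the 10 vector-injected arrays the mean of 4 probe sets shared by haemoglobin genes differed from sham by −0.06 ± 0.34 and −0.00029 ± 0.36, and the MHC change exceeded it with lower 95% bounds of 0.13 and −0.065. Other tests tried for blood were the 8 arrays above sham alone (bounds 0.41 and 0.20, with arrays chosen by their MHC mean), non-transgenic GFP against sham (upper haemoglobin bounds 0.57 and 0.59, against MHC medians of 1.72 and 1.34) and Hba-a1, which was too dim to decide (4.59 to 5.06 on all arrays). Infiltrating lymphocytes may account for part of the pattern, as the lymphocyte mean, taken without Thy1, followed the MHC mean over the 10 vector-injected arrays. In the entorhinal cortex r was 0.906 (rho = 0.939, permutation p = 2e-05 and 0.00023) and in the hippocampus 0.908 (rho = 0.952, permutation p = 0.0006 and 0.00019). Without the 2 arrays farthest from the median r was 0.870 and 0.851, and over 10 relations the adjusted p was 0.0002 and 0.003. Any change that raises immune genes together would give such a relation, so it does not single out lymphocytes. A response to the vector in every injected animal stays open, because 2 of 10 arrays per region did not exceed the sham arrays and sham and vector animals could differ in other ways.

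Thy1 was higher and St13 lower on every transgenic array of both regions, and a difference in Xist class is argued against because the genotypes also lay apart within the high class, with a smallest gap of 0.36 (St13, hippocampus) and Thy1 at 13.65 to 13.99 on transgenic and 12.30 to 12.67 on non-transgenic arrays. T cells, which carry Thy1, are argued against by non-transgenic GFP and sham arrays, mainly in the hippocampus. The other lymphocyte genes read higher with the vector (medians 0.66 and 0.54, against 0.18 and 0.11 in transgenic GFP over all non-transgenic arrays), while Thy1 did not (upper 95% bounds 0.066 and 0.115). None of these genes passed over all genes, and camera did not call the list with an estimated correlation. Without non-transgenic GFP array 1 the lymphocyte list median was 0.31 in the hippocampus. In the entorhinal cortex it was 0.12, below the 0.18 it is set against, so the entorhinal part of this test rests on that array. This test was chosen after one on the highest other lymphocyte gene had not excluded T cells, since Jchain, a gene of antibody-secreting cells, changed more than Thy1 on GFP arrays (smallest excess of Thy1 −1.55, entorhinal cortex), although on BDNF arrays Thy1 exceeded the highest other gene by 0.78 and 1.18. Loss of 1 copy that reaches neighbouring genes is not decided. Both nearest neighbours fell less than St13 in both regions (lower 95% bounds of the difference 0.056 to 0.51), with Slc25a17 at −0.23 and −0.40 and Xpnpep3 at −0.08 and −0.31. The gene beyond Slc25a17, 8430426J06Rik, read 0.02 and 0.01. But the nearest neighbours were dimmer (Slc25a17 7.50 and 7.65, Xpnpep3 7.21 and 7.07, against 11.20 for St13), and log2 differences of dim probe sets are compressed. The dimmest St13 probe set (6.38) read only −0.10 and −0.21. An earlier test had given a run of 2 lower genes, St13 and Slc25a17 (permutation p = 0.0045, 44 of 10000 shuffled gene orders). Mchr1 was lower too (−0.24 and −0.39). All of these were among 10 of 14906 placed genes lower with p under 0.01 in both regions. A shared loss, another difference near St13 and a loss of St13 alone stay open. A transgene transcript read by the Thy1 probe set also stays open, since the gap of 1.07 between the lowest transgenic and the highest non-transgenic array is what it predicts, but any other difference between the genotypes would give the same gap.

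Cwc22 and Pmaip1 were lower, and Galc and Fgf1 higher, on the sham arrays than on all 10 vector-injected arrays in both regions, with gaps of 0.44 to 0.83. The absolute changes of these 4 genes were not larger in the injected entorhinal cortex than in the hippocampus (median difference −0.077). A response strongest in the injected region is not decided by this. The genes were chosen after their values were seen and lie apart in both regions, so genes that respond mainly in the entorhinal cortex could not enter. Inflammation is argued against by a median signed r of −0.00874 with the MHC mean over 8 relations, and Cwc22 moved from 1.11 ± 0.12 to 1.08 ± 0.14 (entorhinal cortex) and from 1.16 ± 0.10 to 1.16 ± 0.15 (hippocampus) with the MHC mean as a covariate, where calls ended because the median standard error rose from 0.127 to 0.143 and from 0.114 to 0.163. Pmaip1 in the hippocampus was the exception (r = 0.525, rho = 0.564, permutation p = 0.118 and 0.0954, adjusted p = 0.395 over 10 relations, r = 0.763 without the 2 farthest arrays). A different genetic background of the sham animals may account for 4 of 4 genes lying apart, and Cwc22 is known to vary in copy number among mouse strains, but sham treatment and background cannot be told apart because the design has no vector-injected animals known to share the sham animals' origin.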

How the results depend on the processing

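The mean of the MHC list as a covariate and the comparison of all 10 vector-injected arrays with sham were chosen after seeing the data, and the other alternatives were fixed before the data were examined. Thy1 was called under each alternative in each comparison of transgenic with non-transgenic arrays within a region, and so was St13 in both entorhinal comparisons with all non-transgenic arrays. BDNF against GFP gave 0 called genes under each alternative in both regions. Outside the left-out arrays, 4243 tests of single genes were counted as unchanged. These were called genes that kept their call and direction, and uncalled genes that stayed uncalled and moved by less than their standard error, whatever their direction. Single genes lost their call in 82 tests, gained one in 25 and, while uncalled, moved by more than their error in 131. Called lists kept their call and direction in 560 tests, lost their call in 261 and reversed in 15. The cause of each change below was not tested except where fewer arrays entered the fit. Signal over background limits dim probe sets, and re-normalization and centring on the array median changed no count of called genes by over 1.5 times.

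With an estimated correlation, camera called 0 lists in each comparison except entorhinal cortex against hippocampus (7 to 1). Fry called 0 except for BDNF against all non-transgenic arrays in the entorhinal cortex (6 to 1) and entorhinal cortex against hippocampus (7 to 15). With the MHC mean as a covariate, called genes for GFP against sham went from 3 to 0 in the entorhinal cortex and from 5 to 0 in the hippocampus, and called lists for BDNF against GFP from 7 to 3 and from 8 to 3. Medians that reversed with it were, in the entorhinal cortex, microglia for BDNF against GFP (0.042), microglia (−0.079), plaque-associated microglia (−0.091) and lymphocytes (−0.087) for transgenic GFP against all non-transgenic arrays, and interferon for GFP against sham (−0.40). In the hippocampus they were interferon for transgenic against non-transgenic GFP (0.090), microglia for transgenic GFP against all non-transgenic arrays (−0.023), and microglia (−0.39), plaque-associated microglia (−0.19), reactive astrocytes (−0.21), interferon (−0.51) and cholesterol (0.049) for GFP against sham.

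Same-numbered arrays did not deviate together throughout. Correlations exceeded 0.1 in 3 of 8 pairs of BDNF and GFP arrays (−0.251 to 0.156), all in the entorhinal cortex. They did so in 3 of 13 pairs of entorhinal and hippocampal arrays (−0.487 to 0.479). Of these, both non-transgenic GFP pairs hold 1 value, 0.470, because 2 arrays deviate from their mean by opposite amounts. Haemoglobin probe sets read 10.90 and 8.70 on entorhinal and 10.88 and 8.94 on hippocampal non-transgenic GFP arrays 1 and 2. The numbers thus do not pair the arrays in general, but pairing of the non-transgenic GFP arrays stays open. With the replicate number as a block, called genes went from 2 to 1 for entorhinal transgenic against non-transgenic GFP, from 6 to 3 for entorhinal BDNF, from 6 to 1 for hippocampal transgenic GFP and from 8 to 1 for hippocampal BDNF against all non-transgenic arrays, and called lists in the last from 16 to 10. As a random block across regions its correlation was −0.0254, and it moved no count by over 1.5 times. With Xist as a covariate, called lists for entorhinal transgenic against non-transgenic GFP went from 2 to 7, called genes against all non-transgenic arrays from 6 to 3 for entorhinal BDNF, from 6 to 3 for hippocampal GFP and from 8 to 1 for hippocampal BDNF, lists in the last from 16 to 9, and the meningeal median for entorhinal transgenic GFP reversed to 0.034.

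With all probe sets tested, called features were 4 in place of 2 for entorhinal transgenic GFP against all non-transgenic arrays, 2 in place of 1 for hippocampal transgenic against non-transgenic GFP, 4 in place of 8 for hippocampal BDNF against all non-transgenic arrays, 11 in place of 5 for hippocampal GFP against sham and 17717 in place of 7748 for entorhinal cortex vs hippocampus. The mean of a gene's probe sets gave 1 in place of 3 for entorhinal GFP against sham, 2 in place of 1 for hippocampal transgenic against non-transgenic GFP, 5 in place of 8 for hippocampal BDNF against all non-transgenic arrays and 3 in place of 5 for hippocampal GFP against sham, and called lists of 0 in place of 1 and 1 in place of 2 for the region differences of BDNF and of the transgene. Array weights gave 5 in place of 2 for entorhinal transgenic GFP and 14 in place of 8 for hippocampal BDNF against all non-transgenic arrays, and 8 in place of 5 for hippocampal GFP against sham. All 26 arrays in 1 fit gave 5 in place of 2 for entorhinal transgenic GFP and 22 in place of 6 for entorhinal BDNF against all non-transgenic arrays, 3 in place of 1 for hippocampal transgenic against non-transgenic GFP and 8 in place of 5 for hippocampal GFP against sham. Only the groups compared gave 3 in place of 6 for entorhinal BDNF and 3 in place of 6 for hippocampal transgenic GFP against all non-transgenic arrays, 2 in place of 1 for hippocampal transgenic against non-transgenic GFP, and 0 in place of 3 and 21 in place of 5 for entorhinal and hippocampal GFP against sham. All 10 vector-injected arrays against sham gave 8 in place of 3 genes in the entorhinal cortex and 11 in place of 5 in the hippocampus, with reversed cholesterol medians of 0.018 and 0.074. No filter gave 0 in place of 1 list for the region difference of BDNF, and the filter at the 50th percentile 1 in place of 2 for that of the transgene. Without splitting the shared arrays, the covariance of the BDNF and transgene effects was −0.00662 in the entorhinal cortex (shuffles −0.0300 to −0.000973) and −0.0102 in the hippocampus. With only the non-transgenic GFP arrays or only the sham arrays it was 0.0105 and −0.00385 in the hippocampus.

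Leaving out each array gave called genes of 1 to 2 for entorhinal transgenic against non-transgenic GFP, 2 to 4 for entorhinal transgenic GFP and 2 to 10 for entorhinal BDNF against all non-transgenic arrays, 0 to 1 for entorhinal GFP against sham, 1 to 5, 1 to 10, 1 to 6 and 2 to 10 for the same hippocampal comparisons, 0 to 1 for the region difference of the transgene (1 without entorhinal non-transgenic GFP array 1) and 7068 to 7950 between regions. Called lists were 1 to 11 and 5 to 10 for BDNF against GFP, 2 to 13 and 6 to 12 for transgenic against non-transgenic GFP, 5 to 14 and 6 to 14 for transgenic GFP against all non-transgenic arrays in entorhinal cortex and hippocampus, 7 to 17 for hippocampal BDNF against all non-transgenic arrays, and 0 to 7 and 0 to 8 for the region differences of BDNF and of the transgene. The hippocampal covariance ranged from −0.00431 to 0.00723. Medians that changed sign ranged from −0.25 to 0.034 (microglia, entorhinal BDNF against GFP), −0.37 to 0.0064 (meninges) for entorhinal transgenic GFP against all non-transgenic arrays, −0.28 to 1.06 (interferon, entorhinal GFP against sham), −0.75 to 0.33 (interferon, hippocampal transgenic against non-transgenic GFP), −0.47 to 0.022 (choroid plexus, hippocampal BDNF against all non-transgenic arrays) and −0.11 to 0.38 (choroid plexus, region difference of the transgene). For microglia in entorhinal transgenic GFP against all non-transgenic arrays the median stayed above 0 (0.015 to 0.31), while camera's direction turned without transgenic GFP array 4. The arrays concerned are named with the comparisons for part of these ranges only. No array is named for interferon in hippocampal transgenic against non-transgenic GFP. The same holds for choroid plexus in hippocampal BDNF against all non-transgenic arrays and for some of the list counts.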

Other observations

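The counts of splits of the arrays given here were planned before the results were seen, and the comparison of split sizes with the MHC mean was chosen afterwards. Each count of splits includes the real split.

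Genes of oligodendrocyte precursors, the dividing cells that form myelinating oligodendrocytes, were lower in transgenic than in all non-transgenic arrays in each comparison. With GFP they were lower in 9 of 9 genes in the entorhinal cortex (median −0.23, camera adjusted p = 1.55e-06; adjusted p = 0.0718 with an estimated correlation) and in 7 of 9 in the hippocampus (−0.15, adjusted p = 2.58e-05; adjusted p = 0.0891 with an estimated correlation). With BDNF they were lower in 9 of 9 (−0.27, adjusted p = 4.09e-05; adjusted p = 0.128 with an estimated correlation and 0.044 by fry) and in 8 of 9 (−0.15, adjusted p = 0.000762; adjusted p = 0.206 with an estimated correlation). The growth factor receptor Pdgfra read −0.32 ± 0.10 with GFP and −0.39 ± 0.10 with BDNF in the entorhinal cortex, and −0.26 ± 0.08 with GFP in the hippocampus, and Lhfpl3 read −0.27 ± 0.09 and −0.36 ± 0.09 in the entorhinal cortex. Adjusted over the list alone 2 and 3 entorhinal genes and 2 hippocampal GFP genes passed, against 0 over all genes. These 4 comparisons share their non-transgenic arrays within a region, and no left-out array ended a call. Transgenic GFP arrays were lower than non-transgenic GFP arrays alone in 7 of 9 genes in the entorhinal cortex (−0.20, camera adjusted p = 0.00825, and 0.358 with an estimated correlation), a call that ended without non-transgenic GFP array 2 (−0.19). The entorhinal means were 8.28 on transgenic GFP, 8.43 on non-transgenic GFP and 8.57 on sham arrays, so part of that difference lay between sham and non-transgenic GFP arrays. In the hippocampus transgenic GFP arrays were lower than non-transgenic GFP arrays in 6 of 9 genes and not called (−0.03, camera adjusted p = 0.119). The hippocampal means were 8.24 on transgenic GFP, 8.27 on non-transgenic GFP and 8.44 on sham arrays, so the hippocampal difference lay mostly between sham and vector-injected arrays.

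Astrocyte genes were lower in 13 of 15 in transgenic GFP arrays in the entorhinal cortex (median −0.09, camera adjusted p = 0.000262; adjusted p = 0.305 with an estimated correlation) and in 13 of 15 in the hippocampus (−0.06, adjusted p = 0.000232; adjusted p = 0.0891 with an estimated correlation). They were lower in 11 of 15 in each region against non-transgenic GFP arrays alone, not called in the entorhinal cortex (−0.02, adjusted p = 0.608) and called in the hippocampus (−0.08, adjusted p = 0.000255; adjusted p = 0.132 with an estimated correlation; −0.04 without non-transgenic GFP array 1). The entorhinal means were 10.51 on transgenic GFP, 10.53 on non-transgenic GFP and 10.66 on sham arrays. Meningeal genes were lower in 13 of 14 in the hippocampus (−0.35, adjusted p = 1.69e-07; adjusted p = 0.111 with an estimated correlation), where Igfbp2 (−0.51 ± 0.14) passed adjusted over the list alone, against 0 over all genes. In the entorhinal cortex the meningeal median of −0.24 (adjusted p = 0.0243; adjusted p = 0.801 with an estimated correlation) became 0.01 without transgenic GFP array 3 and 0.03 with Xist as a covariate, and the call also ended without sham arrays 2 or 3. Meningeal genes were not called against non-transgenic GFP arrays alone in the entorhinal cortex (0.06, adjusted p = 0.945). In the hippocampus they were lower in 12 of 14 (−0.18, adjusted p = 0.000255; adjusted p = 0.591 with an estimated correlation), a call that ended without transgenic GFP array 4 (−0.10) or with Xist as a covariate (−0.01), with −0.37 without transgenic GFP array 1 and −0.29 without non-transgenic GFP array 1. Choroid plexus genes were lower in 14 of 14 in transgenic GFP arrays of the hippocampus (−0.34, adjusted p = 1.49e-05; adjusted p = 0.496 with an estimated correlation), a call that ended without sham array 1 (0.01). They were not called there against non-transgenic GFP arrays alone (0.09, adjusted p = 0.621). Xist lay in the high class on all 10 non-transgenic arrays and on 2 of 4 arrays of each transgenic group. In class, 7 of the 13 pairs of entorhinal and hippocampal arrays with the same group and number matched. The non-transgenic pairs could only match, and of the transgenic pairs only those of BDNF arrays 1 and 3 did.

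Splits of the arrays into groups of the same sizes, the real one counted, were set against the real number of called genes. For BDNF against GFP, 35 of 35 gave as many in the entorhinal cortex (0 real, 4 the highest other) and 35 of 35 in the hippocampus (0 real, 5 the highest other). The region difference of the BDNF effect gave 100 of 100 (0 real, 7 the highest other) and that of the transgene effect 100 of 100 (0 real, 10 the highest other). Every split reaches a real count of 0, so these 4 counts say nothing about chance. For transgenic GFP against all non-transgenic arrays, 3 of 100 splits in the entorhinal cortex (2 real, 3 the highest other) and 3 of 100 in the hippocampus (6 real, 93 the highest other) did so. For transgenic BDNF the figures were 3 of 100 in the entorhinal cortex (6 real, 89 the highest other) and 1 of 100 in the hippocampus (8 real, 4 the highest other). In these 4 comparisons the share is under 0.05, but they are 4 of 9 gene counts, other splits gave as many genes in 3 of them, and single left-out arrays lowered the entorhinal BDNF count to 2 (sham arrays 1 or 2), the hippocampal GFP count to 1 (sham array 2) and the hippocampal BDNF count to 1 (BDNF arrays 1, 2 or 3 or sham arrays 2 or 3). The splits with 89 and 93 genes, and a second entorhinal split of the BDNF comparison with 54, point to a structure of the samples that the groups do not follow. Their sides differed by 1.43, 1.68 and −1.07 in the MHC mean. Splits with differences of 1.52 in the entorhinal cortex and 1.59 in the hippocampus called 1 and 0 genes, so the size of this difference alone does not set the count. Each split also redrew the control groups at random, which alters the spread, so the MHC mean is not excluded as part of that structure. For entorhinal cortex against hippocampus only the real one of 100 splits gave as many (7748 real, 1 the highest other), and chance is excluded there.

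For the number of called gene lists, splits as large were 21 of 35 for BDNF against GFP in the entorhinal cortex (7 real, 13 the highest other) and 23 of 35 in the hippocampus (8 real, 16 the highest other). For transgenic GFP against all non-transgenic arrays they were 28 of 100 (11 real, 15 the highest other) and 34 of 100 (10 real, 16 the highest other). For transgenic BDNF they were 55 of 100 in the entorhinal cortex (6 real, 17 the highest other) and 2 of 100 in the hippocampus (16 real, 16 the highest other). The region differences gave 98 of 100 for BDNF (1 real, 14 the highest other) and 98 of 100 for the transgene (2 real, 16 the highest other), and the regions themselves 60 of 100 (7 real, 16 the highest other). For the list count of transgenic BDNF in the hippocampus the share is under 0.05, but this is 1 of 9 list counts, another split also called 16, and the count was 7 without non-transgenic GFP array 1 and 0 with an estimated correlation. Chance is not excluded for the other list counts.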
